A study of Caenorhabditis elegans with 2 samples.

How the data were processed

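Binding of ELT-1 fused to GFP was measured by ChIP-seq in mixed-stage embryos of strain OP354, in 2 biological replicates of 1 group, per the labels. The labels disagree on the antibody: the antibody field of both samples reads elt-1, while both descriptions state an antibody against GFP, and the descriptions were followed. Replicate numbers were taken from the labels. Chromatin was fragmented by sonication, per the labels. The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here, and the read depth of each sample was unknown, so no precision was derived from depth. Signal tracks were not used here.

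Peak lists were used as deposited, in the narrowPeak format, in 4 kinds for each of the builds ce10 and ce11. Per the text lists of files that go with the records, the authors called a relaxed list (peaks and background, as input for IDR) from each replicate's alignments against a control set shared by both replicates, called another from the pooled replicates, and derived the IDR-thresholded list from these. The relaxed ce11 lists held 30000 peaks for replicate 1, 26001 for replicate 2 and 30000 for the pool. The signal of each peak is the deposited value of column 7, with no stated scale between lists, and was used only to rank, filter and describe peaks within a list. The deposited −log10 q-value was the same (3.53) for all 1400 IDR peaks of ce11 and was not used to rank them. Summits were read from the deposited offset in each interval. Of the IDR peaks, 87.6% were 350 bp wide, and 4 intervals were listed more than once, with different summits, and were kept as separate peaks. Overlapping peaks merged into 1387 regions.

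The ce11 lists were set against the WBcel235 sequence and the Ensembl release 115 annotation, and every peak ended within the length of its chromosome there. Mitochondrial gene symbols came from RefSeq genes on the same assembly. ce10 lists were used only on their own. Coordinates are 1-based on ce11.

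A promoter window ran from 1000 bp upstream to 200 bp downstream of each of 29796 annotated 5′ ends of transcripts of 19985 protein-coding genes. A gene was called occupied when an IDR summit lay in its window, so 1 peak could occupy more than 1 gene. Positions were shuffled within chromosomes 1000 times. Motifs were searched on both strands in windows of 201 bp around summits, against windows of the same size centred 1000 bp to each side that met no IDR peak. Shares were compared with Fisher's exact test, chromosome shares with an exact binomial test over nuclear peaks, and loci with 10000 random windows on the autosomes, which could include the locus itself. Tests were two-sided unless stated, with a threshold of 0.05 and Benjamini-Hochberg adjustment within each family. Intervals are 95% Wilson intervals, or bootstrap intervals from 1000 draws of peaks for the correlation. Peaks and genes are not replicates, so p-values and intervals cover counting error only and say nothing of the spread between embryo cultures. An upper limit for a share of 0 was set at 3 counts of the total. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

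Genes named in the text were chosen by a rule fixed before the data were examined: the 25 protein-coding genes with the highest promoter signal, up to 4 occupied members of each of 18 gene lists by signal, and elt-1, elt-3, lin-26, nhr-25, dpy-7, unc-119, hlh-1, elt-2 and pha-4 in every case. Further genes are marked as chosen later where they appear. The lists covered epidermal regulators, cuticle collagens, epidermal junction and apical matrix genes, hedgehog-related and patched-related genes, epidermal antimicrobial peptides, the GATA factor family, body wall muscle, intestine, pharynx, neurons, germline and early embryo, ribosomal proteins, histones, homeobox ceh genes, nuclear hormone receptors, neuropeptides and chemoreceptors.

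The procedures were tested on simulated data. At 1400 random positions 0 of 2080 6-mers and 0 of 18 gene lists were called. These positions were drawn evenly along the nuclear chromosomes. They did not test for calls that come from the base composition or promoter location of real summits. A site set into 20% of windows ranked 1 among 2080 6-mers. Peaks set on 20% of collagen start sites gave 21.1% occupied collagens, and the list was called.

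Alternatives covered the build, merged peaks, the overlap rule and number of peaks, the correlation measure, promoter windows, motif windows and backgrounds, related motifs, the 50% of IDR peaks with the highest signal, signal tertiles in place of quintiles, gene assignment, random lists matched on the distance to the upstream gene, and locus sizes. To leave out a replicate, the IDR list was replaced by the 1400 relaxed peaks of the other replicate with the highest signal. Leaving out the mitochondrial peaks, and leaving out elt-1 from the 2 lists that hold it, were added after the data were seen. With 1 group there was no contrast between groups to test.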

Results

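ELT-1 is a GATA-type zinc finger transcription factor that specifies the epidermis of the Caenorhabditis elegans embryo. Its binding sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mixed-stage embryos of strain OP354, which carries an integrated transgene that makes ELT-1 fused to GFP and FLAG. The sample descriptions name an antibody against GFP, while the antibody field of both samples names elt-1, and the descriptions were followed here. The series held 1 group of 2 biological replicates, so the comparisons were between the replicates, between peaks and other parts of the genome, and between sets of genes. The main list held 1400 peaks on genome build ce11, thresholded by the submitters with the irreproducible discovery rate (IDR), which concerns reproducibility between replicates. Signal in this list, the peak's own value from the submitters' peak caller, ran from 27.8 to 823 with a median of 39.4. Its lowest value, 27.8227, lay just above 27.8202, the highest among pooled relaxed peaks that overlapped no IDR peak. The list thus matched a cutoff on pooled signal, and a single peak in it need not be strong in both replicates. Read depth was unknown.

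The strongest peak in the genome lay in elt-1 itself, and it ranked 1 in each replicate. Its interval (chromosome IV, 9615413 to 9615949) covered an intron, with a summit at 9615717 and 5 copies of WGATAR (W, A or T; R, A or G), the sequence that GATA factors recognise, within 100 bp. The second summit of elt-1 by signal lay upstream of the gene at 9614229, with a signal of 281 and 3 WGATAR copies. Among nuclear genes other than elt-1, the strongest promoter peaks belonged to dpy-14, a cuticle collagen gene (155, chromosome I, 6843301 to 6843623, intergenic), and to the gene F09A5.3 (154, X, 13141493 to 13141711, intergenic). A peak between hsp-3, which encodes an endoplasmic reticulum chaperone of the HSP70 family, and C15H9.5 had a signal of 151. pmt-2, a methyltransferase gene of phosphatidylcholine synthesis, had one of 142 at its 5′ UTR. The peak between cblc-1 and ZK546.19 reached 137, that at vig-1 reached 123 and that at C06E2.5 reached 121. phdh-1 and gmap-1 followed with 120 and 118.99, sesn-1 and the pair vgln-1 and C08H9.16 with 116 each, and fzr-1 with 115.

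Of the 25 protein-coding genes with the highest promoter signal, 9 lay on the mitochondrial chromosome (COX3, ND4, ND2, COX1, ND3, ND5, ATP6, CYTB and ND1), where 23 of the 1400 peaks fell. Signal in the promoter windows of these genes ran from 277 at COX3 and ND4, which shared a peak, to 132 at ND1. Promoter signal here means position in the window only. The summits counted for COX3, ND4, ND2, ATP6 and CYTB lay in the coding sequence of another gene. The highest mitochondrial signal, 488, lay in the coding sequence of ND5. The median signal was 132 for the 23 mitochondrial peaks and 39.3 for the nuclear peaks. Several of the strongest nuclear peaks lay outside promoter windows, and these were picked out after their values were seen. One in an intron of sprr-1 (X, 15469937 to 15470448) had a signal of 468 and 20 WGATAR matches. An intronic peak of fasn-1, the fatty acid synthase gene (I, 8985841 to 8986236), had 270 and 0 WGATAR matches. An intronic peak of egl-18, a GATA factor gene of the epidermal seam cells (IV, 1911221 to 1911673), had 227, and an intronic peak of ptr-23 (I, 14907932 to 14908229) had 160.

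Around elt-1, 10 IDR summits in 8 separate regions lay within 20 kb, where random autosomal windows of the same size held 0.579 on average (one-sided permutation p = 0.0003 from 10000 windows). These summits ran from 5657 bp upstream of the annotated 5′ end of the gene to 4020 bp downstream of it, and 6 of the 10 had a WGATAR within 100 bp. The count was 14 among the strongest 1400 relaxed peaks of replicate 2 alone and 9 among those of replicate 1 alone. unc-119, the gene that is mutant in this strain, had 0 IDR summits within 20 kb. The origin of any rescuing copy of unc-119 is not given in the sources used here, and a copy from another species would not map there, so this count is no test for copies of the transgene.

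**Figure D1:**
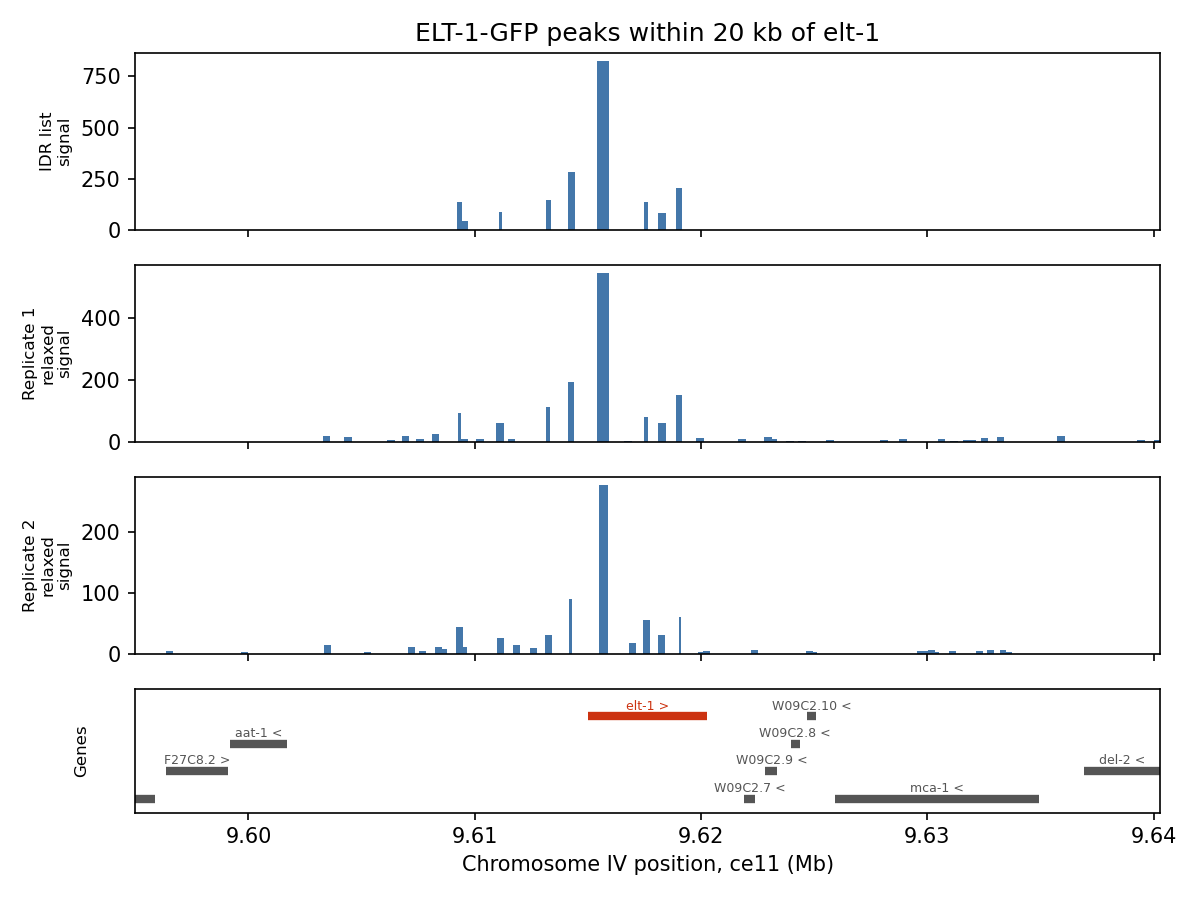
Peak signal (y axis, the submitters' signal value, with a separate scale in each panel) along chromosome IV in Mb on ce11 (x axis), within 20 kb of elt-1, for the IDR list and the relaxed lists of replicates 1 and 2; each bar spans its peak, and the bottom panel shows protein-coding genes with their strand. The tallest peak in every panel is the one in the elt-1 intron, with a signal of 823 in the IDR list.

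Other genes named in advance gave a mixed picture. The collagen gene dpy-7 had a promoter summit with a signal of 71.0 (X, 7537914 to 7538263). nhr-25, a nuclear receptor of epidermal development, had a promoter summit of 35.3 (X, 13007747 to 13008096), and a stronger one, 119.42, in an intron (X, 13012007 to 13012182). elt-3, an epidermal GATA factor gene, had no promoter summit, but a peak of 35.1 lay just past its 3′ end (X, 13941221 to 13941570). lin-26, another epidermal regulator, had none in its window either, and the nearest peak of 32.4 was 1778 bp upstream of its annotated 5′ end (II, 7680245 to 7680594), in an intron of a neighbouring gene. No promoter summit was found at hlh-1 of body wall muscle, elt-2 of the intestine or pha-4 of the pharynx.

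The replicates were compared by position and by rank. Of the 1400 relaxed peaks of replicate 1 with the highest signal, 790 (56.4%, 95% Wilson interval 53.8 to 59.0%) overlapped one of the 1400 highest of replicate 2, against 1.87% on average when positions were shuffled within chromosomes (permutation p = 0.002, two-sided, the smallest that 1000 shuffles can give). Of the 1400 IDR peaks, 1145 (81.8%) overlapped one of the 1400 highest of replicate 1 and 961 (68.6%) one of those of replicate 2. For 775 (55.4%) both held, and for 69 neither did. A relaxed peak of replicate 1 overlapped 1398 IDR peaks, and one of replicate 2 overlapped 1377. Across the 1375 IDR peaks with a relaxed peak in both replicates, Spearman's rho of the replicates' signals was 0.358 (95% bootstrap interval 0.307 to 0.411). Peaks are not independent replicates, so the interval describes these lists only. The IDR list also matched a cutoff on pooled signal, which can lower such a correlation, so rho does not measure agreement over all relaxed peaks. Among the highest peaks of replicate 1, 68.0% of those shared with replicate 2 and 60.8% of the others held WGATAR (Fisher's exact p = 0.0057). For replicate 2 these shares were 68.8% and 51.2% (Fisher's exact p = 1.99e-11).

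GATA sites were concentrated at the summits. WGATAR lay within 100 bp of 913 of 1400 IDR summits (65.2%, Wilson interval 62.7 to 67.7%) and in 1053 of 2644 windows centred 1000 bp to either side (39.8%, 38.0 to 41.7%), an odds ratio of 2.83 (Fisher's exact p = 8.20e-54, two-sided). The density of sites was 7.66 and 6.91 per kb in the 50 bp to the left and right of the summit and 2.78 per kb in the bin that began 1000 bp to its left. At least 2 sites were found at 31.4% of summits and in 10.6% of flanking windows (Fisher's exact p = 1.49e-57). The 4 forms of the site differed. AGATAA was present at 40.9% of summits and in 12.5% of flanks (odds ratio 4.84), and AGATAG at 16.9% and 6.58% (2.89). TGATAA was present at 23.7% and 19.6% (1.28, Fisher's exact p = 0.0023), and TGATAG at 9.57% and 9.19% (1.05, p = 0.69). CGATAA, which is not a form of WGATAR, was present at 18% and 7.68% (2.64), a higher odds ratio than both forms that begin with T. GGATAA was present at 11.1% and 7.72%. HGATAR (H, A, C or T), which adds the forms that begin with C, was present at 76.3% and 46.3%. Its odds ratio of 3.73 was above that of WGATAR, so WGATAR was not the form that best separated summits from flanks. Counted as sites, AGATAA was favoured over TGATAA at summits relative to flanks with an odds ratio of 3.02 (Fisher's exact p = 2.66e-35), a comparison chosen after the shares were seen.

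**Figure D2:**
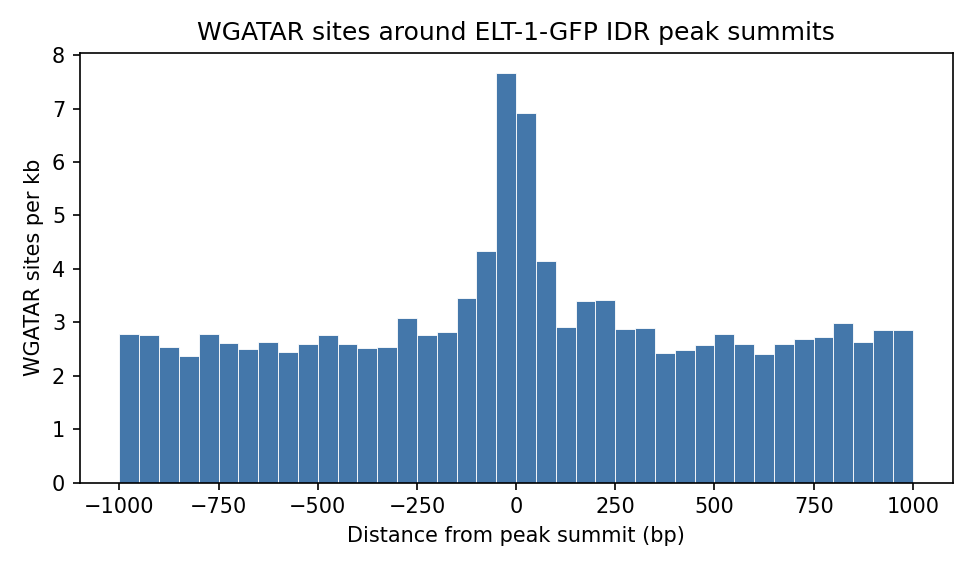
WGATAR sites per kb (y axis) in bins of 50 bp by distance from the IDR summit in bp (x axis), over the 1400 peaks; each bar is 1 bin. The bins on either side of the summit reach 7.66 and 6.91 sites per kb.

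Of 282 scrambles of WGATAR that hold no GATA, 1 had a higher odds ratio than WGATAR. This was WRAGAT, at 2.98, whose last 4 bases are the first 4 of AGATAA. An unguided test of all 2080 6-mers called 969 at a Benjamini-Hochberg adjusted p under 0.05, 585 of them more frequent at summits and 384 less frequent. AGATAA ranked first, and 38 of the 48 6-mers that hold GATA were called more frequent. Sequences without GATA were also frequent: CGTCTC was found at 19.2% of summits and in 5.90% of flanks (odds ratio 3.79, adjusted exact p = 5.49e-35), and GAGAGA at 34.4% and 13.1% (3.48, adjusted exact p = 1.79e-52). Summit windows were richer in G and C than flanks (41.2% against 36.3%), and A-rich and T-rich 6-mers such as AAAATT led those less frequent at summits. Among 8-mers, AGATAAGA stood first, at 8.79% of summits and 0.756% of flanks (odds ratio 12.6), followed by AGACGCAG, at 8.93% and 1.36% (7.10).

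Stronger peaks held GATA sites more often. From the lowest to the highest quintile of IDR peaks by signal, the share with WGATAR was 53.9%, 59.6%, 63.2%, 67.9% and 81.4%, and the highest quintile differed from the lowest with an odds ratio of 3.75 (Fisher's exact p = 3.77e-12, 280 peaks in each). CGTCTC was found in 21.4% of the lowest and 18.9% of the highest quintile (odds ratio 0.856, Fisher's exact p = 0.53). The p-values cover counting error only, since neighbouring peaks and their sequences are not independent.

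**Figure D3:**
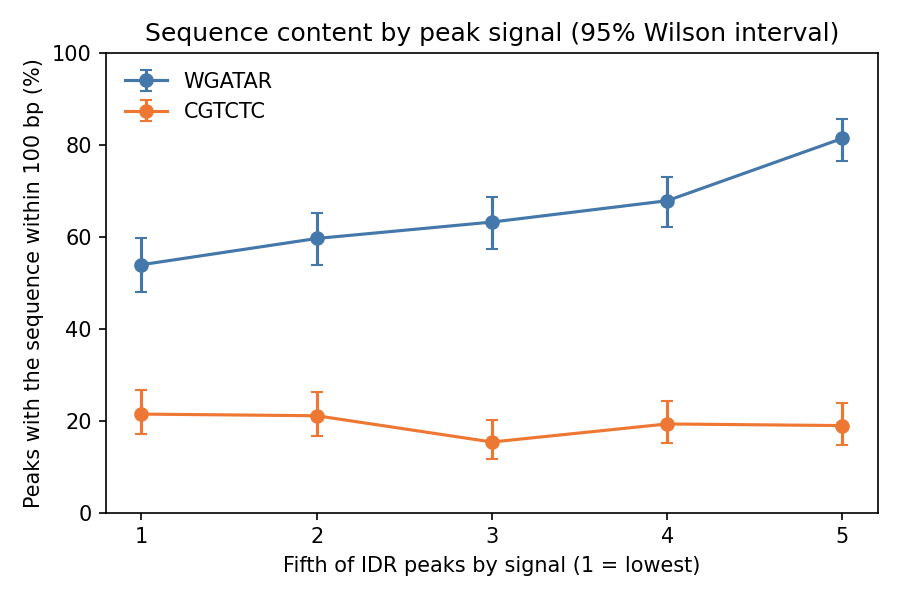
Share of IDR peaks, in %, with WGATAR (blue) or CGTCTC (orange) within 100 bp of the summit (y axis) by quintile of signal, 1 being the lowest (x axis); points are shares of 280 peaks and bars are 95% Wilson intervals. The WGATAR share goes from 53.9% to 81.4%, and that of CGTCTC from 21.4% to 18.9%.

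Peaks favoured promoters and avoided coding sequence. Summits lay from 1000 bp upstream to 200 bp downstream of an annotated protein-coding transcription start site (TSS) for 637 of 1400 peaks (45.5%, Wilson interval 42.9 to 48.1%), against 26.7% of shuffled summits. Other intergenic positions took 26.5% against 21.8%, introns 19.6% against 26.7%, coding sequence 4.36% against 18.8% and 3′ UTRs 0.643% against 2.38%. For each of these 5 classes the permutation p was 0.002, the smallest that 1000 shuffles can give (Benjamini-Hochberg adjusted p = 0.0028 over 7 classes). Many worm transcripts are trans-spliced, so annotated 5′ ends can lie downstream of the true TSS.

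The X chromosome held more peaks than its length would give. It carried 333 of the 1377 nuclear peaks (24.2%, Wilson interval 22.0 to 26.5%) and 17.7% of the nuclear sequence (exact binomial p = 1.35e-09, adjusted exact p = 8.08e-09 over 6 chromosomes), and 13.7% of nuclear protein-coding genes. Chromosome V held fewer, 16.2% of peaks on 20.9% of the sequence (adjusted exact p = 4.07e-05), as did chromosome IV, 15.1% on 17.4% (adjusted exact p = 0.046). Chromosomes I, II and III did not pass the test (adjusted exact p = 1, 0.054 and 0.12).

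Occupied promoters were then counted in 18 gene lists fixed before the data were examined. Of 19985 protein-coding genes, 722 (3.61%) had an IDR summit in the promoter window, and 7 lists differed from all other genes at an adjusted p under 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over 18 lists). Genes of the epidermis were among those with more. Of the cuticle collagens, 16 of 175 were occupied (9.14%, 2.57-fold the share of other genes, adjusted exact p = 0.0028), led by dpy-14 (155), dpy-3 (112), dpy-17 (92.4) and col-107 (75.1). In the list of epidermal junction and apical matrix genes, 5 of 23 were occupied (21.7%, 6.05-fold, adjusted exact p = 0.0043): noah-1, which encodes a zona pellucida domain protein of the embryonic sheath (103), lpr-3 (81.8), the intermediate filament gene ifb-1 (71.1), sym-1 (67.1) and the junction gene dlg-1 (36.5), named after its value was seen. Of the patched-related genes, 4 of 26 were occupied (15.4%, 4.28-fold, adjusted exact p = 0.040), namely ptr-18 (81.2), ptr-15 (60.3), ptr-4 (59.3) and ptr-2 (33.3). Of the epidermal regulators, 3 of 16 were occupied (18.8%, 5.21-fold, adjusted exact p = 0.048): elt-1, which is itself the tagged gene of the transgene, nhr-23 (55.5) and nhr-25.

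The collagen list kept its call in all 8 alternatives, while the calls of the other 3 lists rested on 3 to 5 genes each. Without elt-1, in a comparison added after the data were seen, 2 of 15 epidermal regulators were occupied (3.70-fold, adjusted exact p = 0.20). These 2, nhr-23 and nhr-25, were also among the 34 occupied nuclear hormone receptors, a list at 3.62-fold, so the 2 lists are not separate here. With a window of 500 bp upstream to 100 bp downstream, the adjusted exact p was 0.071 for the junction and matrix list (5.16-fold), 0.25 for the patched-related genes (3.03-fold) and 0.18 for the epidermal regulators (4.93-fold). With 2000 bp upstream of the TSS all 3 passed the test, at 7.995-fold, 4.70-fold and 7.64-fold. With the strongest 50% of peaks the epidermal regulators were at 7.19-fold from 2 genes (adjusted exact p = 0.080). For the patched-related genes and the epidermal regulators the adjusted exact p was 0.14 and 0.21 with replicate 2 alone (3.30-fold and 3.57-fold), and the adjusted permutation p was 0.11 for both against 10000 random lists matched on the distance to the upstream gene, where they were at 3.78-fold and 4.95-fold.

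Of the nuclear hormone receptors, 34 of 269 were occupied (12.6%, 3.62-fold, adjusted exact p = 2.00e-09), led by nhr-119 (110), nhr-168 (97.8), nhr-140 (92.6) and nhr-175 (85.2). The ribosomal protein genes, expressed in all cells, had 15 of 79 occupied (18.99%, 5.35-fold, adjusted exact p = 7.60e-07), led by rpl-3 (82.9), rps-28 (70.9), rpl-15 (54.4) and rpl-35 (51.5). Assigning each peak to its nearest TSS within 2000 bp brought this to 2.54-fold, with an adjusted exact p of 0.020. Of the 14 distinct peaks at these genes, 1 held WGATAR, against 60.5% of the other promoter peaks (adjusted exact p = 8.59e-04, Fisher's exact test over the lists with peaks). The chemoreceptor genes, which are mostly expressed in sensory neurons, were the list with fewer, with 5 of 1232 members (0.406%, 0.106-fold, adjusted exact p = 4.93e-13): srv-7 (70.7), sre-1 (53.1), srh-23 (39.2), sre-23 (33.4) and srh-217 (30.2, named after its value was seen). With replicate 2 alone this was 0.0654-fold, from 3 members, and with 500 bp upstream to 100 bp downstream 0.0300-fold, from 1.

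Markers of the other embryonic tissues had no promoter summit in the main window: 0 of 18 genes of body wall muscle, 0 of 17 of the intestine, 0 of 17 of the pharynx and 0 of 29 of neurons, counts that allow shares of up to 16.7%, 17.6%, 17.6% and 10.3% when the limit is set at 3 counts. In the alternatives, 1 intestine gene was occupied with replicate 2 alone and with the nearest TSS, and 1 neuron gene with 2000 bp upstream and with the nearest TSS, while muscle and pharynx stayed at 0 in all 8. None of these lists differed from other genes (adjusted exact p of 1, 1, 1 and 0.87), and at the average share of 3.61% about 1 member or fewer of each list would be occupied. The lists that did not pass the test also took in germline and early embryo genes (3 of 20, adjusted exact p = 0.076: pie-1, 35.8; spn-4, 29.1; mex-3, 28.6) and epidermal antimicrobial peptides (3 of 22, adjusted exact p = 0.087: nlp-32, 51.2, and nlp-31 and nlp-34, which shared a peak of 30.2). The 3 antimicrobial genes were also the only occupied neuropeptide-named genes, 3 of 102 (adjusted exact p = 1). With replicate 2 alone each of these 3 lists had 1 occupied member: the germline list went from 4.17-fold to 1.43-fold, the antimicrobial list from 3.79-fold to 1.30-fold and the neuropeptides from 0.813-fold to 0.278-fold. With the strongest 50% of peaks the germline list had 0. With windows of 2000 bp upstream of the TSS, the germline list (4 members, 4.07-fold, adjusted exact p = 0.034) and the antimicrobial list (4 members, 3.70-fold, adjusted exact p = 0.038) passed the test. Hedgehog-related genes had 4 of 59 (adjusted exact p = 0.30), with wrt-10 at 63.4, grl-10 at 51.6, wrt-2 at 46.7 and grl-7 at 30.7. Histone genes had 4 of 72 (1.54-fold, adjusted exact p = 0.54), in the pairs his-67 with his-68 (87.7) and his-31 with his-32 (31.5). They had 6 with replicate 2 alone (2.39-fold, adjusted exact p = 0.12) and 2 with the nearest TSS (0.615-fold). The homeobox ceh genes had 1 of 63, ceh-20 at 31.7 (adjusted exact p = 0.94), and 0 with replicate 1 alone, with the strongest 50% of peaks or with 500 bp upstream to 100 bp downstream. The GATA factor family had 1 of 12, elt-1 itself (2.31-fold, adjusted exact p = 0.54). It had 2 with replicate 2 alone (4.76-fold, adjusted exact p = 0.14), and passed the test with windows of 2000 bp upstream of the TSS (3 members, adjusted exact p = 0.038) and with the nearest TSS (4 members, adjusted exact p = 0.0039).

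**Figure D4:**
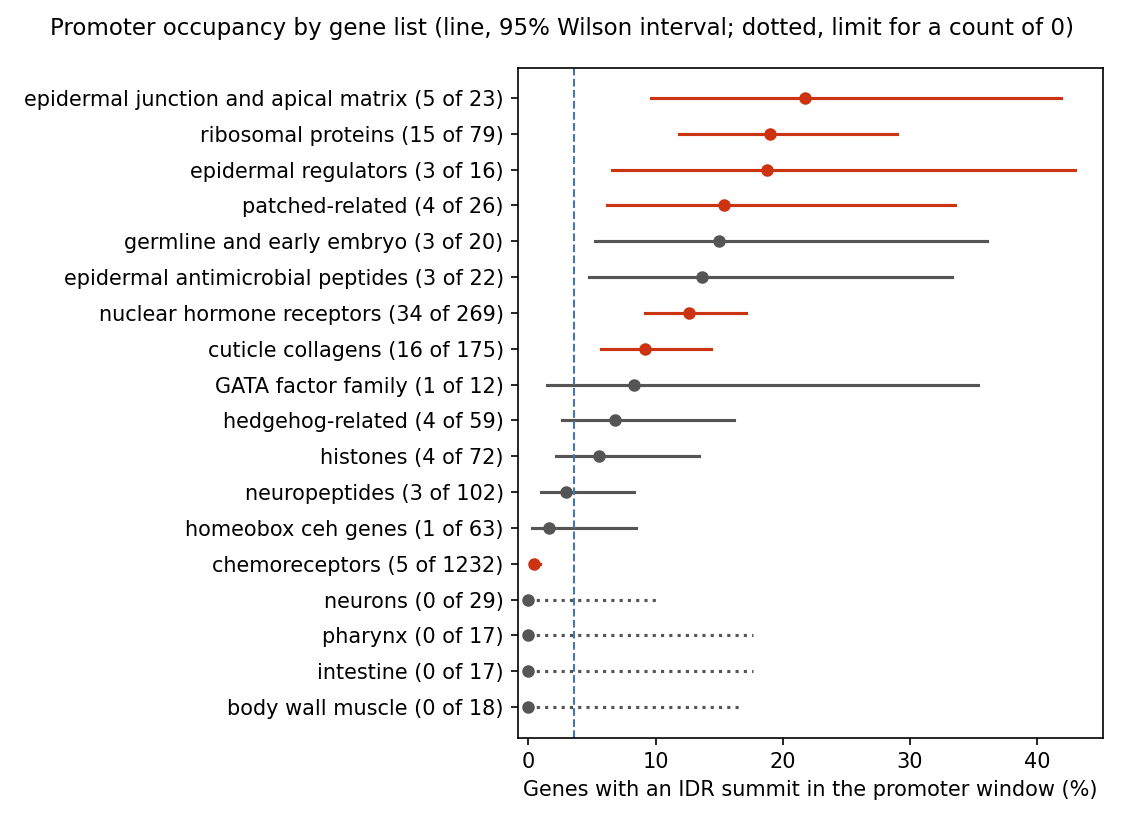
Share of protein-coding genes in each list with an IDR summit in the promoter window, in % (x axis), by gene list with occupied and total members in parentheses (y axis); points are shares, solid lines are 95% Wilson intervals, dotted lines run to the limit of 3 counts for lists at 0, red marks an adjusted p under 0.05, and the dashed line is the 3.61% of all protein-coding genes. The red lists lie above the dashed line, except the chemoreceptors at 0.406%.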

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

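The tests on mitochondrial coverage, on the lowest quintile of signal and on CGTCTC outside promoter windows, and the choice of peaks below the IDR list, were made only after the results they concern had been seen.

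The strongest pooled relaxed peaks outside the IDR list, which the comparisons above did not report on, held WGATAR more often than their flanks. Of the 1400 pooled peaks outside the IDR list with the highest signal (18.3 to 27.8), 726 held WGATAR within 100 bp of the summit, 51.9%. Their own flanking windows held it in 37.3% (odds ratio 1.81, Fisher's exact p = 9.33e-19). The IDR peaks exceeded them, with an odds ratio of 1.74 (Fisher's exact p = 8.88e-13). The 2 sets are adjacent ranges of pooled signal, and the lowest quintile of IDR peaks held WGATAR at 53.9%. The comparison therefore repeats the rise of WGATAR with signal and is no separate test of the IDR threshold. The promoter share of the peaks below the IDR list was 47.1%. Over all 28368 pooled relaxed peaks outside the IDR list, WGATAR was found in 39.1%, against 39.8% of the flanking windows of the IDR peaks.

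The cluster of 10 IDR summits at elt-1 has more than 1 candidate explanation. The strain carries a transgene of elt-1, and extra copies of the region would raise the background over the whole inserted piece. Relaxed pooled peaks 5 to 20 kb from the gene had a median signal of 9.49, at percentile 82.4 of random autosomal windows of the same shape (median 7.78), between the bounds set for and against this explanation, although 22 peaks lay there against 9.12 in an average random window. The range also held IDR summits of the cluster itself, 5657 and 5452 bp upstream of the gene, and peaks there were not left out. The extent of the insert is not given in the sources used here, so this range may lie outside it. Binding of ELT-1 to GATA sites near its own gene was tested by the WGATAR share of the 10 summits, 60%, against 39.8% in flanking windows (Fisher's exact p = 0.21), which 10 summits could not settle. Transgene copies and binding cannot be told apart with these peak lists.

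The 23 mitochondrial IDR peaks covered 50.2% of the mitochondrial chromosome of 13794 bp. Mitochondrial DNA is present in many copies, and reads from it could give peaks with no binding by ELT-1. Relaxed peaks covered 48.1% of it in replicate 1 and 45.8% in replicate 2, between the 50% set for this explanation and the 20% set against it. Both bounds were set after the IDR peaks were seen. The share under peaks also depends on the number and width of called peaks (27 and 28 here), so it does not measure read coverage and cannot decide. WGATAR was found at 65.2% of the 23 summits and in 50.7% of random mitochondrial windows (permutation p = 0.24). These values leave the explanation open, and no biological explanation was tested.

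WGATAR was absent within 100 bp of the summit in 487 IDR peaks. Some of these held a related site, since HGATAR lay at 1068 of the 1400 summits against 913 for WGATAR. The bare sequence GATA lay at 1265 summits (90.4%) and in 73.5% of flanks. Background at the low end of the list stays open as a cause. The lowest quintile of signal held WGATAR more often than the flanks (53.9% against 39.8%, Fisher's exact p = 7.13e-06), but the bound set against the explanation was wrong, because a mixture of sites and background would also exceed the flanks, as the peaks below the IDR list did. In the highest quintile, 52 of 280 peaks also lacked WGATAR. CGTCTC was more frequent in peaks without WGATAR than in those with it, 22.2% against 17.6%, with an odds ratio of 1.33 (Fisher's exact p = 0.046). Whether it is a second promoter element stays open, because in nuclear peaks without WGATAR it was found in 20.6% of 253 inside promoter windows and 24.8% of 226 outside them (odds ratio 0.785, Fisher's exact p = 0.28). Outside promoter windows, GC content alone is argued against as the whole source of CGTCTC: its share was 2.46 times that of windows matched on GC content only (10.1% of 2260 draws from 1983 distinct windows, Fisher's exact p = 2.38e-09). Promoter position was not excluded in those 226 peaks, because the windows cover only annotated 5′ ends of protein-coding transcripts. Inside promoter windows, base composition and promoter position stay open, because promoter peaks without WGATAR held CGTCTC 1.57 times as often as promoter windows of unoccupied genes matched on GC content (20.6% against 13.1% of 2530 draws from 2080 distinct windows, Fisher's exact p = 0.0021), between the bounds set for and against. Neither WGATAR nor CGTCTC was present in 379 peaks (27.1%), a count that does not exclude other GATA forms.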

How the results depend on the processing

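Leaving out the mitochondrial peaks or elt-1 was chosen after the data were seen, and all other alternatives before. Of 60 alternatives to the summary results, 56 kept direction and call. For a count this meant staying within 1.5 times the main count, and for the correlation staying inside its bootstrap interval. The WGATAR share was above its background in all 10 alternatives (odds ratios from 1.28 for TGATAA alone to 3.74), the promoter share in all 7 (32.6 to 59.1%), and the X share in all 5 (22.9 to 24.8%). The overlap of the replicates ranged from 49.7 to 56.6% over 6 alternatives. Among the exceptions, Pearson r of log2 signal was 0.479 against rho of 0.358. With the 50% of peaks of highest signal, which halved the windows tested, 629 6-mers were called against 969. With the window of 500 bp upstream to 100 bp downstream, 4 gene lists were called against 7. The last exception was a change of direction against random windows at unc-119, given below. Within the 1.5 times, 1079 6-mers were called against relaxed peaks outside the IDR list (874 of them as in the main test), and the lists called were 10 with 2000 bp upstream, 8 with the nearest TSS, 6 with the strongest peaks, 5 against matched lists and 5 to 7 when a replicate was left out. Around unc-119 the count was 0 to 2 when a replicate was left out, and 2 did not differ from random windows (one-sided permutation p = 0.14). Among 146 alternatives over single gene lists, 127 kept direction and call. The call was lost in 9, for the epidermal regulators (adjusted p from 1.33e-05 to 0.21 over all settings), patched-related genes (0.0031 to 0.25) and the junction and matrix list (7.26e-09 to 0.071), and gained in 4, for the GATA factor, antimicrobial and germline lists. Direction changed in 6, never in a called list: with the nearest TSS, intestine was 1.31-fold, histones 0.615-fold and ceh genes 1.06-fold, with the strongest peaks the germline list was 0-fold, without elt-1 the GATA factor list was 0-fold, and the intestine list ran from 0-fold to 1.68-fold when a replicate was left out. The cause was not tested. The genes chosen by the rule, together with the 25 nuclear genes of highest promoter signal, gave 73 with a promoter summit. Not all of them are named in the text. Of these 73, 65 kept a promoter summit with replicate 2 alone and 69 with replicate 1 alone. With the window of 500 bp upstream to 100 bp downstream 55 kept it, and with the strongest peaks 60. nhr-25 was among those lost with replicate 2 alone. The IDR count, the overlap and the correlation need both replicates and have no value without one. No paired analysis was possible because the series holds 1 group. Without read depth, it could not be asked whether the motif shares of the replicates, 61.1% for replicate 2 alone and 64.9% for replicate 1 alone, follow their depth.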

Other observations

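Small RNA genes drew peaks with few GATA sites. Within 100 bp of tRNA genes lay 19 IDR summits, against 2.58 on average after shuffling, and of these 21.1% held WGATAR, against 65.8% of other peaks (Fisher's exact p = 9.56e-05). Near snoRNA genes there were 21 summits, against 1.58, with WGATAR at 28.6% (Fisher's exact p = 7.40e-04). Near snRNA genes there were 5, against 0.519, and 0 of the 5 held WGATAR (Fisher's exact p = 0.005). The permutation p was 0.002 for each of the 3 classes, the smallest that 1000 shuffles can give, and these classes were chosen after the data were seen.

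X and autosomal peaks did not differ past the threshold in the 3 features compared. WGATAR was found at 68.5% of X summits and 64.2% of autosomal summits (Fisher's exact p = 0.17, adjusted p = 0.25 over 3 features), and promoter windows held 42.9% and 45.6% (adjusted p = 0.41). CGTCTC was found at 15.3% of X summits and 20.9% of autosomal summits (odds ratio 0.685, Fisher's exact p = 0.026, adjusted p = 0.079).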
